A study of Mus musculus with 18 samples.

How the data were processed

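Total RNA of whole testes from repro9/repro9 mutants and wild-type mice at 14 and 17 dpp was extracted with a Qiagen RNeasy-type kit, and biotinylated cRNA was made from 6 ug of it, per the labels. It was hybridised to an Affymetrix whole-genome mouse expression array and processed with Affymetrix GCOS, per the series' design text, and MAS5 is named in the submitters' processing notes, where its version is not given. The deposited values are MAS5 signal intensity on a linear scale, with 1 value per probe set and array and none missing. Detection calls were not analysed here. On 11 arrays the mean without the lowest and highest 2% of values was about 499.9, which is the mark of scaling to a common target. On the other 7, all of 17 dpp, it was about 394.8, and their values were whole multiples of a step of 0.07899 (tolerance of 0.02 steps, tested on values under 50). That pattern would follow from a common factor of 0.7899 (−0.34 on the log2 scale), whose purpose is not given in the sources used here. No normalization between arrays is stated and none was added in the main model.

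The table held 45101 probe sets. The 64 Affymetrix control probe sets were left out of the tests and used for quality checks, which left 45037. Of these, 34945 were annotated to 1 gene, 932 to several and 9160 to none. A probe set was tested if its signal lay above its own array's 40th percentile on at least 3 arrays, the size of the smallest group, and 34764 probe sets passed. That percentile ran from 49.2 to 93.4 over the arrays. A gene was represented by its brightest tested probe set annotated to that gene alone, which gave 15307 genes, of which 15274 matched the reference table by Entrez ID. The reference table (assembly GRCm38.p6) served only for gene names, chromosomes and the order of genes along a chromosome, and no coordinates were used.

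Log2 signal was fitted with limma 3.58.1 in R 4.3.3 as 1 mean per group over all 18 arrays (14 residual degrees of freedom), with empirical Bayes moderation and an intensity trend. Tests were two-sided with Benjamini-Hochberg adjustment over the 34764 probe sets and a threshold of 0.05. Contrasts were mutant minus wild type at 14 dpp, at 17 dpp and as the mean of both, their difference (the interaction), and 17 minus 14 dpp in each genotype. Each ± is the standard error from limma unless SD is named. The tests, the filter, the lists and the rule for named genes were fixed before the data were examined.

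The array sets were defined after that, from the β-actin 3' to 5' ratio, with bounds at 1.9 and 10. The block fit added the set as a fixed term (12 residual degrees of freedom). The within-set fits used a mean per group and set with the spread shared by all arrays, so that a group with 1 array in a set was assumed to vary like the others. Arrays of 1 group correlated at 0.818 to 0.956 within a set and at 0.615 to 0.912 across sets, and no pair of arrays was identical. Replicate numbers were checked for pairing by the correlation, across probe sets, of the deviations of same-numbered arrays from their group means. At 14 dpp the 3 pairs gave 0.283, 0.355 and 0.385, and each pair lay in 1 array set. Differently numbered mutant and wild-type arrays of 1 set gave 0.288 to 0.384 there, and arrays of different sets gave negative values. The correlations therefore follow the array sets and do not show that the numbers pair. At 17 dpp the 5 pairs gave from −0.227 to 0.777 and were not treated as pairs.

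There were 23 lists of genes, with 529 members written down, 471 on the array and 444 tested. The tested members were 403 different genes, 38 of which stand in more than 1 list. The lists were the MYB family, piRNA pathway, synaptonemal complex and recombination, pachytene spermatocyte markers, meiotic division and G2/M, round spermatid and acrosome, cilium and flagellum axoneme, testis isoforms of energy metabolism, spermatocyte transcription regulators, testis histones and chromatin factors, spermatogonia, preleptotene to zygotene genes, X-linked genes expressed in spermatogonia, Y-linked genes, autosomal retrogenes of X-linked genes, Sertoli, Leydig, peritubular myoid, macrophage, endothelial and epididymis markers, apoptosis and p53 response, and heat shock and immediate early genes. Of the pachytene markers 14 of 27, of the energy isoforms 6 of 15, and of the preleptotene to zygotene genes 14 of 22 also stand in another list, while the Sertoli, Leydig, macrophage, endothelial and epididymis lists share no member. All X-linked genes (511 tested) and all Y-linked genes (8 tested) were tested as further sets.

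Lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over the 23 lists, and with fry. Camera compares a list with all other genes, so its direction is relative to them. Printed adjusted p values of lists are those with an estimated correlation. X-linked and autosomal genes were compared by Fisher's exact test, two-sided. That test counts genes as independent, which genes measured on the same arrays are not, so its p values do not measure the spread between arrays. The named genes were Mybl1, the 6 largest rises and 6 largest falls per genotype comparison among called genes whose replicates did not overlap, up to 2 called members of each list, and the 4 largest each way for the age comparisons and the interaction. Other members of lists and families, and Nipbl and Pik3cd, were picked as examples after their values were seen.

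The fits were tested on simulated data with 200 changed of 34764 probe sets and with the array set differences of the real data. Without a block 4.48% of 2-fold, 38.8% of 4-fold and 60.6% of 8-fold changes were recovered for the genotype difference at 17 dpp, and 23.9%, 71.6% and 75.8% with the block. At 14 dpp the shares were 4.48%, 25.4% and 47%, and 22.4%, 47.8% and 80.3% with the block. For the interaction they were 0%, 17.9% and 36.4%, and 5.97%, 44.8% and 60.6% with the block. For age in wild type the fit without a block made 62 false calls and the blocked fit 6, and for age in mutants 130 and 2. The simulated noise was independent between probe sets, with 1 SD per probe set on all arrays. These counts therefore do not give the error rate on the real arrays, where labels exchanged within sets gave up to 5331 calls at 17 dpp with the block.

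Alternatives fixed in advance were quantile normalization, a common median, no filter, a filter at the 60th percentile (23687 probe sets), 16 or 64 added before log2, no intensity trend, array weights, only the arrays of the groups compared, the replicate number as a block, no probe sets that can match several transcripts, a threshold of 0.025, the methods' two-way model, the mean of a gene's probe sets, and leaving out each array. Alternatives chosen after seeing the data were the array set block, alone, with quantile normalization or with the Gapdh 3' to 5' ratio as a covariate, set 3 on the common trimmed mean, no set 3 arrays, and fits within sets. Every genotype count was also compared with counts from other divisions of the same arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.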

Results

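Gene expression was profiled in whole testes of juvenile mice homozygous for repro9, an allele of Mybl1, and of wild-type mice, at 14 and 17 days postpartum (dpp). Mybl1 encodes A-MYB, a transcription factor of meiotic male germ cells. Per the series' design text, the younger age was chosen for its share of early and middle pachytene spermatocytes and the older age for late pachytene and diplotene cells. The data comprised 18 Affymetrix arrays, 5 from mutants and 3 from wild type at 14 dpp and 5 from each genotype at 17 dpp. The median signal per array ran from 88.7 to 149. The filter on low signal left 34764 probe sets, which represented 15307 genes. The number of arrays limits the precision of every value. The series' text gives at least 3 mice per genotype, but no source ties an array to 1 animal, so the replicates may not be shown to be separate animals.

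Control probe sets for β-actin divided the arrays into 3 sets that the labels do not name. The ratio of the 3' to the 5' β-actin signal, a measure of how far labelled transcripts reach toward their 5' ends, was 2.31 to 2.92 on 7 arrays, called set 1. Set 1 held replicates 1 and 2 of the mutants and of the wild type at 14 dpp, replicates 1 and 2 of the mutants at 17 dpp and replicate 1 of the wild type at 17 dpp. The ratio was 1.45 to 1.495 on the other 4 arrays of 14 dpp, called set 2, and 102.6 to 125.1 on the other 7 arrays of 17 dpp, called set 3. The first principal component, with 49% of the variance, separated set 3 (scores of 147 to 217) from the other arrays (−131 to −85.5). Each set held both genotypes, so genotypes could also be compared with the array set as a block and within sets. Ages could be compared within a set only on set 1, with 1 wild-type array of 17 dpp and 2 of 14 dpp and with 2 mutant arrays of each age. The array sets were found after the data were examined.

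**Figure D1:**
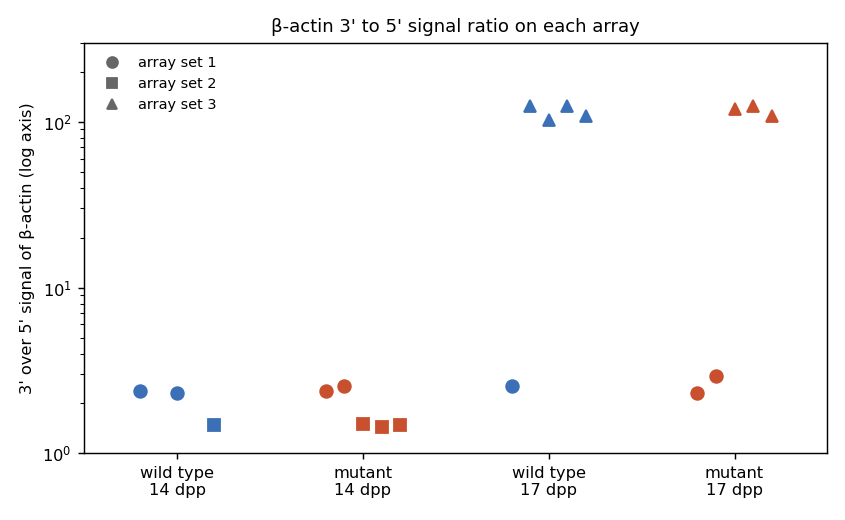
The ratio of 3' to 5' signal of the β-actin control probe sets (log axis) for each of the 18 arrays, by group. The 7 arrays of set 3 lie between 102.6 and 125.1, and the other 11 arrays at or below 2.92.

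Mybl1 itself, on chromosome 1, gave (by its brighter probe set) a lower signal in each mutant array than in any wild-type array of the same age. At 14 dpp its geometric mean signal was 126 in mutants (n = 5) and 637 in wild type (n = 3), a log2 difference of −2.33 ± 0.52 (SE) that did not pass the threshold (adjusted p = 0.112). At 17 dpp the signal was 167 in mutants (n = 5) and 1831 in wild type (n = 5), a fall of 11.0-fold (log2 difference −3.46 ± 0.45, adjusted p = 5.25e-05). On the log2 scale the arrays ran from 6.09 to 7.96 in mutants and from 8.999 to 9.60 in wild type at 14 dpp, and from 6.38 to 8.19 and from 10.07 to 11.95 at 17 dpp. With the array set as a block the differences were −2.07 (adjusted p = 0.0655) and −3.54 (adjusted p = 4.48e-06). The difference at 14 dpp was −1.39 within set 1 (adjusted p = 0.622) and −2.99 within set 2 (adjusted p = 0.0321). It also passed with array weights (−2.66, adjusted p = 6.46e-06), without the set 3 arrays (0.0295) and with the block and the Gapdh ratio (−2.09, adjusted p = 0.0257), and the adjusted p over all other alternatives ran up to 0.864, without wild-type replicate 2 of 14 dpp. The difference at 17 dpp was −1.92 within set 1 (adjusted p = 0.076, and 0.141 without the set 3 arrays) and −4.17 within set 3 (adjusted p = 1.25e-06). In wild type Mybl1 rose with age by 1.52 ± 0.52 (adjusted p = 0.0448), a call that ended with the array set block (1.51, adjusted p = 0.121). In mutants the age difference of Mybl1 was 0.40 ± 0.45 (adjusted p = 0.581). The dimmer Mybl1 probe set gave −2.04 at 14 dpp (adjusted p = 1) and −1.03 at 17 dpp (adjusted p = 0.348). Where the probe sets lie relative to the repro9 change is not given in the sources used here, so the level of Mybl1 does not check the labels.

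The comparison of genotypes at 14 dpp addresses which transcripts differ without normal A-MYB when the wild-type testis holds early and middle pachytene spermatocytes. Genes known from pachytene spermatocytes were lower in the mutants. Piwil1, the PIWI protein that binds pachytene piRNAs, fell 17.8-fold, from a geometric mean signal of 1071 in wild type (n = 3) to 60.3 in mutants (n = 5; log2 difference −4.15 ± 0.39, adjusted p = 6.22e-05). Adam2, a sperm surface protein of the ADAM family, fell 53.3-fold, from 954 to 17.9 (−5.74 ± 0.68, adjusted p = 3.65e-04). Ldhc, the lactate dehydrogenase subunit of male germ cells, fell 51.1-fold, from 2846 to 55.7 (log2 difference ± SE −5.67 ± 0.89). Further large falls were those of Mroh4 (−6.43 ± 0.96), Ldhal6b, a testis relative of lactate dehydrogenase (−5.85 ± 0.74), Morc2b, a chromatin protein needed for meiosis (−5.81 ± 0.94), and 1700006A11Rik (−5.65 ± 0.62). Mutant signals of these 4 genes (7.07 to 15.6) and of Adam2 lay below 49.2, the lowest 40th percentile of an array, so the sizes of the falls depend on the background. Those of Piwil1 and Ldhc lay below the 40th percentiles of the mutant arrays of 14 dpp (68.4 to 93.4), so the sizes of these falls may depend on it too.

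By the lists fixed in advance, 5 of 27 tested pachytene spermatocyte markers fell at 14 dpp (Adam2, Ldhc, Piwil1, the chaperone Clgn and the heat shock protein Hspa2), none rose, and 26 of the 27 had a negative difference (median −0.93, adjusted p = 2.6e-05 with an estimated correlation). Of 15 testis isoforms of energy metabolism, 5 fell, among them the glycerol kinase Gk2 (−5.40 ± 1.01), the cytochrome c oxidase subunit Cox8c (−2.53 ± 0.46) and testis cytochrome c, Cyct (−2.003 ± 0.34), with a list median of −2.003 (adjusted p = 4.5e-06). Of 24 spermatocyte transcription regulators, 3 fell, namely Morc2b, the transcription factor Rfx4 (−3.86 ± 0.62) and the general transcription factor relative Gtf2a1l (−3.17 ± 0.48), and the list median was −0.11 (adjusted p = 0.00442 with an estimated correlation). Meig1, needed for assembly of the sperm flagellum, fell by 2.61 ± 0.30 as the only called member of 27 axoneme genes (list median −1.24, adjusted p = 0.00199 with an estimated correlation). Piwil1 was the only called member of 21 piRNA pathway genes (median −0.40, adjusted p = 0.0399 with an estimated correlation). None of 10 genes listed as autosomal retrogenes of X-linked genes passed in limma (4 at an unadjusted p under 0.05), and all 10 differences were negative (median −0.99, adjusted p = 0.00382 with an estimated correlation). Adjusted over the list alone, 12 pachytene markers, 10 energy genes, 9 axoneme genes, 3 transcription regulators, 2 retrogenes and 1 piRNA gene fell. On a common median the transcription regulators (0.0538) and piRNA genes (0.166) did not pass, and the latter also failed with the mean of probe sets (0.0592) and the replicate block (0.12). Tesmin, a metallothionein-like protein of meiotic cells, fell by 3.15 ± 0.45, and Crisp2, a protein of the acrosome and sperm tail, by 4.84 ± 0.84, each as the only called member of the meiotic division list (adjusted p = 0.2 with an estimated correlation) and of the spermatid list (adjusted p = 0.455 with an estimated correlation).

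No list of somatic cell markers had a member called by limma at 14 dpp, and none of their members had an unadjusted p under 0.05. The medians were 0.04 for Sertoli cells (mean −0.08), 0.02 for Leydig cells, 0.31 for peritubular myoid cells, 0.28 for macrophages and 0.25 for endothelial cells, with adjusted p from 0.153 to 0.94 with an estimated correlation. Spermatogonia genes had a median of 0.09 (adjusted p = 0.354) and preleptotene to zygotene genes one of 0.02 (mean −0.03, adjusted p = 0.94), and 1 member of each list had an unadjusted p under 0.05. The p53 response list (median 0.01, mean −0.02), the heat shock list (−0.01) and the epididymis list (−0.07) held no member at an unadjusted p under 0.05. The preset correlation also called the MYB family, the synaptonemal complex, the meiotic division, X-linked spermatogonial, Y-linked, myoid and macrophage lists, and none of these calls held with an estimated correlation (adjusted p from 0.109 to 0.354).

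At 14 dpp limma called 68 of 34764 probe sets, 68 lower and 0 higher, for 49 genes, with 696 at an unadjusted p under 0.05. Of the 68, 63 were lower by more than 4-fold. With the array set block, 128 were called on the same arrays (4 higher and 124 lower), including all 68. Array weights turned the balance, with 5357 called, 3409 higher and 1948 lower. Within set 1 (2 mutant and 2 wild-type arrays) 84 were called, 70 of them lower, and within set 2 (3 mutant arrays and 1 wild-type array) 31 were called, 28 of them lower. The differences of Piwil1 were −3.94 within set 1 and −4.17 within set 2. Without wild-type replicate 2 the count was 24, and the adjusted p rose to 0.0576 for Mroh4, 0.0768 for Ldhc, 0.0801 for Morc2b, 0.108 for Rfx4 and 0.168 for Crisp2. Without wild-type replicate 3 it was 0.0522 for Morc2b and Rfx4 and 0.0927 for Crisp2. Within set 2 the adjusted p was 0.292 for Mroh4, 0.212 for Ldhal6b and Ldhc, 0.631 for Morc2b, 0.321 for Crisp2 and 0.288 for Rfx4. It was also 0.306 for Rfx4 within set 1 and 0.0911 for Crisp2 with only the arrays of 14 dpp.

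The comparison of genotypes at 17 dpp addresses the same question when the wild-type testis holds late pachytene and diplotene spermatocytes. Many transcripts of meiotic germ cells were lower in the mutants. Ldhc fell 229-fold, from a geometric mean signal of 36090 in wild type (n = 5) to 158 in mutants (n = 5; log2 difference −7.84 ± 0.77, adjusted p = 2.29e-06). Adam2 fell 211-fold, from 12330 to 58.5 (−7.72 ± 0.59, adjusted p = 1.48e-07), and Piwil1 fell 116-fold, from 7319 to 63.4 (−6.85 ± 0.34, adjusted p = 2.04e-09). These 2 mutant signals lay within the range of the 40th percentiles of the mutant arrays of 17 dpp (52.2 to 90.0), so these folds may depend on the background. The other largest falls were those of Tmbim7 (log2 difference −7.86 ± 0.75, with a mutant mean signal of 9.86 near background), Gk2 (−7.69 ± 0.88), 4930544G11Rik (−7.57 ± 0.83) and Spag6l, a central pair protein of the axoneme (−7.51 ± 0.67), the last 3 with mutant signals of 9.98 to 29.9, also below 49.2. Among called genes whose replicates did not overlap, the largest rises were those of Cavin4, Frrs1, Gdap1, Gbx1, Neb and Lefty1. They were smaller than these falls and reached mutant signals of 69.5 to 158. Frrs1 (2.82), Gdap1 (2.37) and Neb (2.20) are taken up below. Cavin4, a caveolar protein of muscle, rose 9.27-fold from 8.79 to 81.4 (3.21 ± 0.53, adjusted p = 6.84e-04), the homeobox gene Gbx1 by 2.20 ± 0.49, and Lefty1, an inhibitor of Nodal signalling, by 2.14 ± 0.42, with wild-type signals of Gbx1 (19.8) and Lefty1 (26.5) also below 49.2. The calls of Cavin4, Gbx1 and Lefty1 depended on set 3. Without its arrays Cavin4 had 2.45 (adjusted p = 0.161), Gbx1 0.93 (0.548) and Lefty1 1.02 (0.271), and with only the arrays of 17 dpp Gbx1 (0.081) and Lefty1 (0.0804) did not pass.

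Among pachytene spermatocyte markers 22 of 27 fell at 17 dpp and none rose (median −2.97, adjusted p = 1.23e-04 with an estimated correlation). Of 15 energy metabolism isoforms 11 fell (median −3.39, adjusted p = 1.23e-04), among them Ldhc, Gk2 and Pgk2, the phosphoglycerate kinase of sperm (−5.66 ± 0.84). Of 27 axoneme genes 14 fell, such as Spag16 (−6.04 ± 0.86), Spag17 (−5.92 ± 1.07) and the dynein heavy chain Dnah8 (−4.46 ± 0.48), with a list median of −2.27 (adjusted p = 0.00404 with an estimated correlation). Spag17 had −2.57 without the set 3 arrays (adjusted p = 0.376) and within set 1 (0.587). Of 10 genes listed as autosomal retrogenes 5 fell, including the poly(A)-binding protein Pabpc2 (−5.73 ± 0.78) and the centrin Cetn1 (−4.59 ± 0.38; list median −2.09, adjusted p = 0.0118). Of 21 piRNA pathway genes 7 fell, among them Piwil1, Mael, a piRNA and transposon silencing factor (−1.58 ± 0.25), the Tudor protein Tdrd12 (−1.56 ± 0.37) and the germ cell helicase Ddx4 (−1.30 ± 0.32; list median −1.17, adjusted p = 0.015). Of 24 spermatocyte transcription regulators 9 fell, including Morc2b (−6.87 ± 0.82), Rfx4 (−5.73 ± 0.54) and Crem, a regulator of spermatid genes (−1.19 ± 0.31; list median −0.60, adjusted p = 0.015). Adjusted over the list alone, 24 pachytene markers, 12 energy genes, 21 axoneme genes, 7 retrogenes and 10 piRNA genes fell, and 10 transcription regulators fell while 4 rose. On a common median the piRNA genes and the transcription regulators did not pass (adjusted p = 0.093 for each list).

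Other germ cell lists moved in part. Of 22 round spermatid and acrosome markers 6 fell, such as Crisp2 (−7.04 ± 0.73), Pgam2, a phosphoglycerate mutase (−5.37 ± 0.91), and the acrosomal protease Acr (−2.66 ± 0.47), with a median of −0.64 (adjusted p = 0.0552 with an estimated correlation, and 0.0389 on a common median). Of 36 synaptonemal complex and recombination genes 3 fell, Psmc3ip, a recombinase cofactor (−2.33 ± 0.26), Mlh3, a crossover factor (−1.36 ± 0.21), and Meiob (−1.03), while 3 rose, Msh5, a crossover factor (2.50 ± 0.71), the recombinase Dmc1 (0.99 ± 0.28) and Tex15 (0.81 ± 0.22). The median of that list was −0.53 (adjusted p = 0.198 with an estimated correlation). Of 34 meiotic division and G2/M genes 5 fell, including Tesmin (−2.96 ± 0.39) and the kinase Nek2 (−2.46 ± 0.58), and the cyclin Ccnb3 rose by 1.64 ± 0.26 (median −0.18, adjusted p = 0.346 with an estimated correlation). For Msh5 and for Nek2, 1 other probe set had the opposite sign and was not called. Of 20 testis histone and chromatin genes Morc2b, Mdc1, a mediator of the DNA damage response (−1.71 ± 0.21), and the kinase Atr (−1.19) fell and Scml2, an X-linked Polycomb protein, rose (1.19 ± 0.33). The median of that list was 0.07, its mean −0.11 and its set test pointed down (adjusted p = 0.348 with an estimated correlation), and the median was −0.06 after quantile normalization. In the MYB family Mybl1 fell, while Mybl2 gave 0.13 and Myb 0.16, so the list's median (0.13) and mean (−1.06) differed in sign, and the median was −0.17 after quantile normalization (adjusted p = 0.272 with an estimated correlation).

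Genes of earlier germ cells did not fall as a group. The median over all probe sets was 0.25, so their positive values are in part shared with genes at large. Of 26 spermatogonia genes 1 fell, Id4, a marker of stem cells that spermatocytes also express (−2.72 ± 0.24), and 24 had a positive difference (median 0.69, adjusted p = 0.174 with an estimated correlation). Of 22 preleptotene to zygotene genes Tex15, Dmc1 and the replication licensing factor Cdt1 (1.12 ± 0.30) rose, and Dmrtc2, a regulator of the pachytene sex chromosomes (−1.83 ± 0.40), and Meiob fell (median 0.60, adjusted p = 0.332).

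Genes on the X chromosome were higher in mutants at 17 dpp. The test called 56 of 511 X-linked genes higher (11%) and 252 of 14686 autosomal genes (1.72%), an odds ratio of 7.05 (95% confidence interval 5.1 to 9.6, Fisher's exact test, two-sided, adjusted p = 5.85e-25). It called 0 X-linked genes lower, against 888 autosomal ones (6.05%, Fisher's exact p = 5.79e-14). Genes are not independent replicates, so these Fisher p values do not measure the spread between arrays. The median difference of autosomal genes was 0.24. Of the 511 X-linked differences 469 were positive (median 0.68, adjusted p = 0.00476 with an estimated correlation, 0.035 with quantile normalization and 0.0912, not passing, on a common median), and 125 genes rose when adjusted over the list alone. With the array set block 257 X-linked genes (50.3%) and 1934 autosomal genes (13.2%) were higher, and the X-linked median was 0.78 within set 1 and 0.65 within set 3. Of 31 X-linked genes expressed in spermatogonia all had positive differences and 5 rose, among them the transketolase relative Tktl1 (1.34 ± 0.28), Scml2, the demethylase Kdm5c (0.88 ± 0.24) and Hprt (0.78 ± 0.18), with a median of 0.75 (adjusted p = 0.0295 with an estimated correlation, but 0.0816 with the array set block, 0.093 with the replicate block and 0.211 on a common median). Of 6 Y-linked genes 3 rose, the ubiquitin enzymes Uba1y (1.04 ± 0.23) and Usp9y (0.99 ± 0.22) and the initiation factor Eif2s3y (0.90 ± 0.20), and all 6 had positive differences (median 0.95, adjusted p = 0.199 with an estimated correlation). Some of these calls depended on the scaling, though the differences stayed positive. With quantile normalization and on a common median Usp9y had 0.78 and 0.85 (adjusted p = 0.149 and 0.0665) and Scml2 1.09 and 1.04 (0.0722 and 0.101). Tktl1 had 1.19 on a common median (0.057), and none of these passed.

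**Figure D2:**
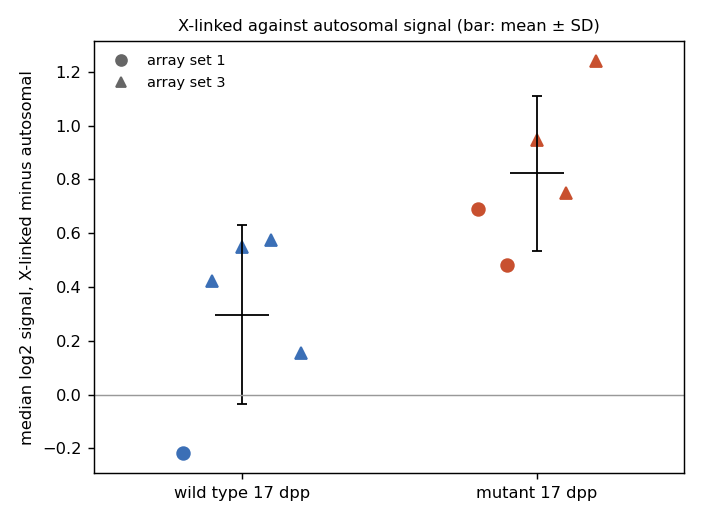
Median log2 signal of 511 X-linked genes minus that of 14686 autosomal genes on each 17 dpp array, with the mean ± SD per genotype (n = 5 and 5). Mutant arrays run from 0.482 to 1.24 and wild-type arrays from −0.218 to 0.574, and within set 1 and within set 3 each mutant array lies above each wild-type array.

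Markers of somatic cells tended to positive values at 17 dpp, and few passed. The median difference was 0.25 over all probe sets and 0.24 over autosomal genes, so part of these positive values is shared with genes at large. None of 26 Sertoli cell markers was called by limma (4 at an unadjusted p under 0.05), and 25 had positive differences (median 0.50, adjusted p = 0.0938 with an estimated correlation). None of 10 Leydig cell markers was called (3 at an unadjusted p under 0.05, median 0.86, adjusted p = 0.242). Of 15 macrophage and immune genes all had positive differences and 1 rose, the colony stimulating factor receptor Csf1r (0.90 ± 0.25; median 1.03, adjusted p = 0.19 with an estimated correlation). Of 16 peritubular myoid genes the proteoglycan Dcn rose (0.94 ± 0.21; median 0.52, adjusted p = 0.303). None of 11 endothelial and blood genes (median 0.39, adjusted p = 0.656) and none of 4 epididymis genes (median −0.18, adjusted p = 0.485) was called or had an unadjusted p under 0.05. Of 22 apoptosis and p53 response genes the cell cycle inhibitor Cdkn1a (1.25 ± 0.29) and Ccng1 (0.90 ± 0.23) rose (median 0.54, adjusted p = 0.131 with an estimated correlation), and of 16 heat shock and immediate early genes the chaperone Dnajb1 fell (−1.15 ± 0.23; median 0.48, adjusted p = 0.432). With the array set block 9 Sertoli, 2 Leydig, 5 macrophage, 4 myoid and 5 p53 response genes were higher, with adjusted p of 0.114 for the Sertoli list and 0.0816 for the p53 list with an estimated correlation. Scaling ended the calls of most of the rises named here, as Ccng1 (adjusted p = 0.213 and 0.137) and Csf1r (0.0602 and 0.108) did not pass with quantile normalization or on a common median, and Cdkn1a (0.0585) and Dcn (0.0631) not on a common median. A lost call does not show that the difference was absent.

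**Figure D3:**
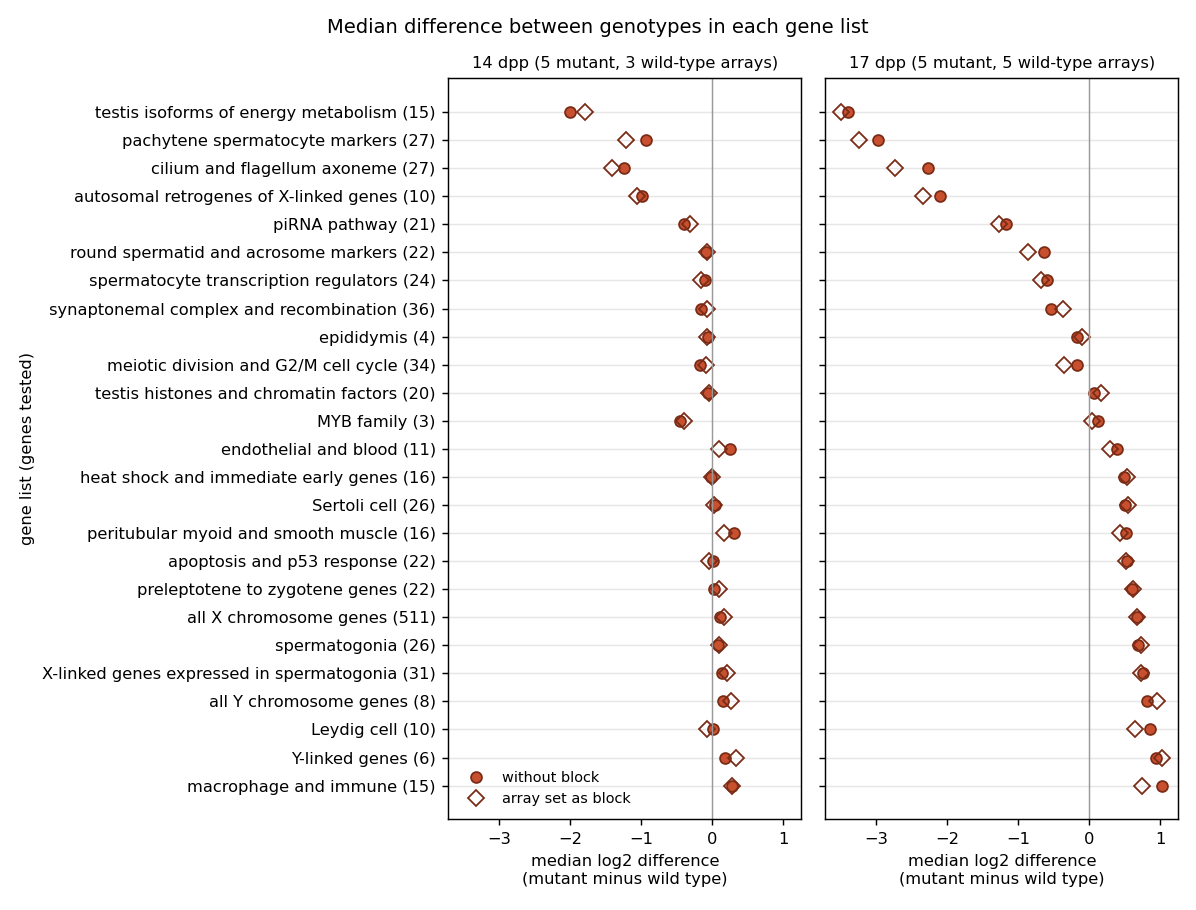
Median log2 difference (mutant minus wild type) of the tested members of each fixed list at 14 and 17 dpp, without a block and with the array set block. The pachytene list lies at −0.93 and −2.97 without a block, and the X-linked spermatogonial list at 0.14 and 0.75.

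At 17 dpp limma called 1854 probe sets, 513 higher and 1341 lower, for 311 and 892 genes, and 772 of the lower and 82 of the higher ones differed by more than 4-fold. With the array set block 6550 were called (3751 higher and 2799 lower), including all 513 and all 1341. Within set 1 (2 mutant arrays and 1 wild-type array) 990 were called, 903 of them lower, and within set 3 (3 mutant and 4 wild-type arrays) 4006, 2110 of them lower. Set 3 alone called 474 of the 513 higher and 1220 of the 1341 lower probe sets. These fits reuse the arrays behind the 1854 calls, most of them of set 3, so such overlaps are no independent check. Within set 3 the Gapdh 3' to 5' ratio, a sign of RNA quality, was 9.59, 5.24 and 18.5 in mutants and 15.9, 15.4, 7.29 and 13.5 in wild type. Most mutant arrays thus had a lower ratio than most wild-type arrays, so RNA quality and genotype are partly confounded there. With this ratio as a covariate beside the block 8008 probe sets were called, including all 1854, but with so few arrays a covariate need not part them fully. The median difference of all probe sets was 0.25, against 0.105 after quantile normalization and 0.108 on a common median, and the counts were then 311 higher and 1470 lower, and 114 higher and 1341 lower. Without wild-type replicate 1 the count was 3947, with rises in the majority (2347 higher and 1600 lower), and without wild-type replicate 5 it was 1206, and with only the arrays of 17 dpp in the model it was 862, 25 of them higher. Among the named genes no fall lost its call when a single array was left out, whereas Msh5, Scml2, Frrs1, a reductase (2.82 ± 0.80), Csf1r, the muscle protein Neb (2.20 ± 0.60), Cdt1, Ccng1 and Gdap1 (2.37 ± 0.58) lost their calls without 1 of 15, 14, 14, 10, 7, 6, 4 and 1 single arrays, with adjusted p up to 0.129. With quantile normalization and on a common median the adjusted p was 0.0834 and 0.094 for Frrs1, 0.0682 and 0.0585 for Gdap1, 0.0857 and 0.0776 for Neb and 0.0611 and 0.0839 for Msh5, and Cdt1 did not pass on a common median (0.117).

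Further calls at 17 dpp ended when arrays were left out of the model. With only the arrays of 17 dpp Frrs1, Gdap1, Neb, Msh5, Nek2, Dmrtc2, Cdt1, Scml2, Uba1y, Usp9y, Dcn, Csf1r, Cdkn1a, Ccng1 and Dnajb1 did not pass (adjusted p from 0.0514 to 0.262). Without the set 3 arrays Frrs1 had 1.70, Gdap1 0.91, Neb 0.82 and Msh5 0.51, and these and Cdt1, Tktl1, Uba1y and Cdkn1a did not pass (adjusted p from 0.0878 to 0.708). Within set 1, with 2 mutant arrays and 1 wild-type array, Mael (0.276), Nek2 (0.2), Mdc1 (0.0518), Dmrtc2 (0.447), Dcn (0.289), Csf1r (0.358) and Dnajb1 (0.101) did not pass either.

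The mean of the genotype differences at both ages addresses the genotype effect in the sense of the series' 2-factor model. It called 964 probe sets, 78 higher and 886 lower, for 44 and 626 genes, and with the array set block 2991 (1213 higher and 1778 lower). Of the pachytene markers 21 of 27 fell (median −2.15), of the energy isoforms 11 of 15 (median −2.53), of the axoneme genes 13 of 27 (median −1.60) and of the retrogenes 5 of 10 (median −1.72), each with an adjusted p at or below 0.00367 with an estimated correlation. X-linked genes had a median of 0.40, with 10 of 511 higher (adjusted p = 0.00508 with an estimated correlation, and 0.1 on a common median) and 156 with the block. The histone list had a median of 0.16, a mean of −0.19 and a set test that pointed down (adjusted p = 0.311 with an estimated correlation). The methods' two-way model gave 866 probe sets at the 0.025 threshold of the series' text and 1127 at 0.05.

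The probe sets lower at 14 dpp were also lower at 17 dpp. All 68 were among the 1341 lower at 17 dpp, where 2.62 would be shared if the calls were independent, and with the array set block 124 of 124 were shared (9.98 if independent). Across 34764 probe sets the genotype differences at the 2 ages had a Pearson correlation of 0.364 and a Spearman correlation of 0.185, and 0.434 and 0.279 with the block. Probe sets are not independent replicates, so these correlations carry no p.

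The interaction tests whether the genotype difference changed between the ages. Falls were deeper at 17 than at 14 dpp for Piwil1, by −2.70 (adjusted p = 0.0352), and for Meig1, by −2.49 (adjusted p = 0.0129). The largest interactions were those of Ccdc7a (−6.32 ± 1.20), Lin7a, a scaffold protein (−5.98 ± 1.11), Gm7444 (−5.65 ± 0.76) and the cilium and flagellum gene Cfap299 (−4.91 ± 0.88). Geometric mean signals of Ccdc7a (5.13 to 15.97) and Lin7a (12.4 to 47.2) lay below 49.2 in all groups but the wild type of 17 dpp, and those of Gm7444 (47.0) and Cfap299 (23.4) did in mutants of 17 dpp, so the sizes and their order depend in part on the background. The interaction passed for 3 lists with an estimated correlation, the pachytene markers (median −1.71, adjusted p = 0.00274, 2 of 27 genes called), the energy isoforms (−1.52, adjusted p = 0.0131, 0 of 15 called by limma and 6 at an unadjusted p under 0.05) and the axoneme genes (−1.51, adjusted p = 0.0481, 1 of 27 called). Adjusted over the list alone 12, 5 and 7 of these genes passed. X-linked genes moved the other way (median 0.55, adjusted p = 0.0157 with an estimated correlation), with 0 of 511 called by limma and 47 at an unadjusted p under 0.05, but did not pass with quantile normalization (adjusted p = 0.105) or on a common median (adjusted p = 0.185). No other list passed (adjusted p from 0.0701 upward). The meiotic division list had a median of 0.18 and a set test that pointed down, and the histone list a median of −0.12 and a mean of 0.17.

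The interaction was called for 71 probe sets, all lower, for 55 genes, with 1951 at an unadjusted p under 0.05, and for 416 with the array set block (22 higher and 394 lower). With the block the pachytene (adjusted p = 0.0356), energy (0.0394) and axoneme lists (0.0443) also passed with an estimated correlation, as did the piRNA and retrogene lists (0.0356 each). Without wild-type replicate 1, 2 or 3 of 14 dpp limma called 0 (with 1198 at an unadjusted p under 0.05), 31 or 12 probe sets, without mutant replicate 1, 2, 3, 4 or 5 of 14 dpp 40, 33, 33, 31 or 29, without mutant replicate 2 of 17 dpp 40, and without wild-type replicate 2, 3, 4 or 5 of 17 dpp 26, 32, 133 or 34. Ccdc7a, Lin7a, Cfap299 and Gm7444 lost their calls without 1 of 12, 10, 10 and 1 single arrays, with adjusted p up to 0.175.

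The comparison of 17 with 14 dpp in wild type addresses the transcripts that appear as spermatocytes advance. Ms4a19 rose by 6.80 ± 1.08 (SE, n = 5 and 3), Toporsl by 6.61 ± 1.26, Tex24 by 6.49 ± 1.18 and 4930403D09Rik by 6.40 ± 0.89, and all 4 were also called with the array set block (6.27, 5.72, 5.31 and 6.23). Their geometric mean signals in wild type at 14 dpp, 6.63, 5.17, 2.70 and 14.7, lay below 49.2, so the sizes of the rises depend on the background. Pachytene markers rose in 16 of 27 cases (median 1.79, adjusted p = 0.0185 with an estimated correlation), for example Clgn by 1.67 ± 0.35, and energy isoforms in 7 of 15 (median 1.60, adjusted p = 0.025), for example Gk2 by 3.67 ± 1.01. The pachytene and energy lists did not pass with quantile normalization (adjusted p = 0.0547 and 0.0751), on a common median (0.104 each) or with the replicate block (0.054 each). Axoneme genes rose in 12 of 27 cases (median 0.87, adjusted p = 0.23 with an estimated correlation). With the array set block these 3 lists had 18, 7 and 11 rises, the retrogenes had 4 of 10 and the piRNA genes 7 of 21, each list with an adjusted p of 0.028 with an estimated correlation. X-linked genes fell more often than autosomal ones, 143 of 511 (28%) against 2743 of 14686 (18.7%), and with the block 86 (16.8%) against 607 (4.13%, odds ratio 4.69, Fisher's exact adjusted p = 7.53e-26).

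Falls with age in wild type were fewer with the array set block (1589 probe sets) or on a common median (1315) than without either (5750), which does not part the array sets from scaling or from power lost to the block. Mfap4, a protein of elastic fibres, fell by 6.78 ± 1.35 and by 2.46 with the array set block (adjusted p = 0.00259). Mtch1, a mitochondrial outer membrane protein, fell by 6.87 ± 1.75 and by 1.21 with the block. Apoe, an apolipoprotein, fell by 6.40 ± 1.91 without a block and had −0.05 with it (adjusted p = 0.97), and the chloride channel Clcn2 fell by 6.23 ± 1.81 and had −0.43 (adjusted p = 0.792). At 17 dpp the wild-type signals of these 4 genes (18.2 to 28.8) were also below 49.2. Sertoli markers fell in 11 of 26 cases and with the block in 2, myoid genes in 8 of 16 and then in 5, and spermatogonia genes in 11 of 26 and then in 2, and none of these lists passed with an estimated correlation with or without the block (adjusted p from 0.114 to 0.263). Y-linked genes had a median of 0.12 without a block, with none at an unadjusted p under 0.05, and −0.81 with it. Against a median of all probe sets below 0, the set test pointed up for lists with a negative median, namely the MYB family (−0.72), meiotic division (−0.40) and histone lists (−0.48), and the epididymis list had a median of 0.05 and a mean of −0.02. Apoe, Clcn2 and Mtch1 lost their calls without 1 of 6, 5 and 2 single arrays, with adjusted p up to 0.0962. Within set 1, with 1 array of 17 dpp, Toporsl (0.15), Tex24 (0.109), Mtch1 (0.238) and Mfap4 (0.0703) did not pass.

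In wild type limma called 7438 probe sets with age, 1688 higher and 5750 lower, for 1081 and 2891 genes, and 2654 with the array set block (1065 higher and 1589 lower). The block kept 672 of the 1688 rises and 536 of the 5750 falls. Within set 1 (1 array of 17 dpp and 2 of 14 dpp) 759 were called, 424 of them higher. The median of all probe sets was −0.44, against 0.07 after quantile normalization (2819 higher and 2826 lower) and −0.08 on a common median (2401 higher and 1315 lower). On set 1 the 17 dpp arrays also stood apart, as 142 probe sets lay more than 1 log2 unit outside all other arrays irrespective of genotype, such as 1 for the cohesin loader Nipbl (7.07 to 7.29 against 11.05 to 13.04 elsewhere). The count without wild-type replicate 1, 2 or 3 of 14 dpp was 1286, 2755 or 1576, and without wild-type replicate 1, 2, 3 or 5 of 17 dpp it was 12474, 4696, 4272 or 3382.

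The comparison of ages in mutants addresses the same change without normal A-MYB. The extracellular matrix genes Col1a1, a collagen of interstitial fibroblasts (−4.38 ± 0.58 SE, n = 5 and 5), and Mfap4 (−5.47 ± 1.17) fell and were also called with the array set block (−3.13 and −2.20). Osr2, a zinc finger transcription factor (−4.21 ± 1.06), and Dcakd (−4.00 ± 0.90) were called lower without the block only. With the block they had −1.01 and −1.98 (adjusted p = 0.506 and 0.436). G530011O06Rik, on the X chromosome, rose by 3.39 ± 0.56, the kinase Cdkl4 by 2.88 ± 0.70, the phosphodiesterase Pde10a by 2.57 ± 0.50 and the ubiquitin ligase Marchf11 by 2.52 ± 0.55. With the block the differences were 2.16, 1.75, 1.84 and 2.50, and none of the 4 rises passed (adjusted p from 0.0564 to 0.537). In mutants the lower mean signals of Osr2 (47.2), G530011O06Rik (47.1), Cdkl4 (7.66) and Marchf11 (10.9) lay below 49.2, so these sizes depend on the background too. For Cdkl4, 1 other probe set had the opposite sign and was not called. Pachytene markers rose in 1 of 27 cases and fell in 1 (median 0.35), energy isoforms in 0 of 15 (median 0.57) and axoneme genes in 0 of 27 (median −0.18, but 0.21 within set 1), and no fixed list passed with an estimated correlation (adjusted p from 0.613 upward). Without that estimate the preset correlation called the myoid, Y-linked and synaptonemal complex lists, with medians of −0.86, 0.66 and 0.21, of which the last had a mean of −0.01. The piRNA, spermatid, axoneme, energy and histone lists held 0 called members in limma and 7, 3, 6, 5 and 4 at an unadjusted p under 0.05. The set test pointed up, relative to all genes, for lists with negative medians, such as the spermatid (−0.39), axoneme (−0.18) and heat shock lists (−0.24), and the macrophage list (median 0.01), the epididymis list (0.03) and all X-linked genes (0.02) had means of −0.41, −0.27 and −0.11.

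In mutants limma called 667 probe sets with age, 147 higher and 520 lower, for 99 and 171 genes, with 10248 at an unadjusted p under 0.05, and 478 with the array set block (49 higher and 429 lower). The block kept 7 of the 147 rises and 93 of the 520 falls, and set 1 alone (2 arrays of each age) called 238, 226 of them lower. The median of all probe sets was −0.34, against 0.10 after quantile normalization (792 higher and 524 lower) and −0.01 on a common median (1395 higher and 329 lower). With set 3 on the common trimmed mean the calls were 171 higher and 315 lower in mutants and 2139 higher and 4167 lower in wild type. Without mutant replicate 3, 4 or 5 of 14 dpp the count was 97, 116 or 108, without mutant replicate 1, 2, 3, 4 or 5 of 17 dpp 6951, 6138, 166, 224 or 205, and without wild-type replicate 1 or 2 of 14 dpp or 1 or 3 of 17 dpp 391, 412, 4322 or 442. Osr2, Cdkl4, Dcakd, Mfap4, Marchf11 and Pde10a lost their calls without 1 of 15, 11, 7, 6, 6 and 2 single arrays, with adjusted p up to 0.133. With only the mutant arrays Mfap4 (0.054), Osr2 (0.0661), Dcakd (0.0577), Cdkl4 (0.0858) and Marchf11 (0.0803) did not pass.

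The age differences of wild type and mutants shared 79 rises, of 1688 and 147, and 404 falls, of 5750 and 520, where 7.14 and 86 would be shared if the calls were independent. Across probe sets the age differences of the 2 genotypes had a Pearson correlation of 0.741 and a Spearman correlation of 0.733, which fell to 0.333 and 0.398 on set 1 alone. Within set 1 the median age difference of the pachytene markers was 1.75 in wild type and 0.32 in mutants. That of the axoneme genes was 2.76 and 0.21, that of the energy isoforms 1.83 and 0.36, and that of the retrogenes 1.18 and 0.19. These 4 lists were picked because their wild-type median within set 1 was over 1. Their high wild-type values follow from that choice, so these medians do not test a difference between genotypes. The wild-type values also rest on 1 array of the older age, which lay far from its group in other values.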

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

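The tests of a scaling factor, of lost 5' signal, of the X-linked genes and of absent transcripts were chosen after their results were seen, as were the array sets. The divisions within array sets for the interaction and the mean over both ages were too. The tests of the hybridisation spikes, of the age falls and of the other divisions were not.

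In 7 of 104 groups of 4 or 5 arrays examined, 1 array lay far from the others, where 5.2 would by chance (about 1 in 20), and 3 of the 7 were wild-type replicate 1 of 17 dpp, the only set 1 array of its group. On that array the β-actin 3' to 5' ratio was 2.549, against 102.6 to 125.1 on the other 4, the trimmed mean signal 499.9 against 394.8, and the log2 signal of Spag17 5.279 against 9.712 to 10.99. At 14 dpp Morc2b was 5.248 on mutant replicate 5 (1.9 to 2.796 on the others) and Rfx4 2.062 on mutant replicate 4 (4.239 to 4.837). At 17 dpp Id4 was 9.875 on mutant replicate 4 (10.67 to 10.85) and Csf1r 12.56 on mutant replicate 3 (11.72 to 11.89).

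The genotype difference changed between the ages, by the interaction test, for Piwil1 (−2.70, adjusted p = 0.0352), Meig1 (−2.49, adjusted p = 0.0129), Ccdc7a (−6.32, adjusted p = 0.0346), Lin7a (−5.98, adjusted p = 0.0323), Gm7444 (−5.65, adjusted p = 0.0114) and Cfap299 (−4.91, adjusted p = 0.0305). It also changed, by the median with an estimated correlation, for pachytene markers (−1.71, adjusted p = 0.00274), axoneme genes (−1.51, adjusted p = 0.0481), energy isoforms (−1.52, adjusted p = 0.0131) and all X-linked genes (0.55, adjusted p = 0.0157). These interactions were not equally stable. Over its alternatives the adjusted p ran from 0.00596 to 0.175 for Ccdc7a (15 of 34 did not pass), from 0.000469 to 0.151 for Lin7a (13 of 34), from 0.000645 to 0.0753 for Gm7444 (1 of 33) and from 0.00129 to 0.127 for Cfap299 (11 of 34), highest without wild-type replicate 1 of 14 dpp or, for Lin7a, without the set 3 arrays. Piwil1 and Meig1 were refitted only with the array set block (−2.84, adjusted p = 0.00753, and −2.42, adjusted p = 0.00367). Over 5 alternatives the adjusted p ran from 0.00167 to 0.0356 for pachytene markers, from 0.0145 to 0.0627 for axoneme genes, which did not pass with the replicate block, and from 0.0143 to 0.0394 for energy isoforms. For X-linked genes it ran from 0.0102 to 0.185 over 7, of which 2 did not pass, quantile normalization (0.105) and a common median (0.185).

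The 7 arrays of set 3 stood apart from all others. A scaling factor alone is excluded, since on a common median the set 3 minus set 1 differences in mutants at 17 dpp had an SD over probe sets 2.20 times that between set 1 arrays (1.787 against 0.811), although set 3 arrays also differed among themselves (1.322). Hybridisation or scanning is excluded as the cause of the high β-actin 3' to 5' ratio, since the spikes added after labelling had 3' to 5' ratios in set 3 of 0.960 times those elsewhere (0.887 to 1.07 over 4 spikes). A change that moves both ends of a transcript alike would not show in these ratios, so it stays open for the other differences of set 3. Loss of 5' signal during RNA preparation or labelling may be the source, since the same quotient had a median of 9.03 over 4 transcripts of the sample, with 51.1 for β-actin, 14.5 for Gapdh and 3.54 for Tfrc. Pcx went the other way (0.289), which stays open, and the labels name no batch.

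Behind the higher X-linked signal in mutants at 17 dpp, a difference between array sets is excluded as the whole cause, since the X-linked median exceeded the autosomal one by 0.47 in set 3 and by 0.57 in set 1. Scaling is excluded only as the cause of the excess over autosomal genes. A factor per array leaves the X-linked minus autosomal median per array unchanged by construction. After quantile normalization that median differed between genotypes by 0.641 (0.624 before; exact permutation within sets, two-sided, p = 0.009524, the smallest that 105 arrangements can give, n = 5 and 5). Calls of single X-linked genes are not covered by that test. That test was adopted after a first, the set test with an estimated correlation, had given adjusted p of 0.035 with quantile normalization and 0.0912 on a common median, which left scaling undecided. A lower share of pachytene cells, in which the X chromosome is silenced, may account for much of the pattern, since the X-linked median lay 0.122 above that of 99 autosomal genes of 6 lists of other testis cells (0.673 against 0.551), and no difference among those lists was detected (permutation p = 0.471; medians from 0.362 for endothelial to 0.742 for macrophage genes). The excess itself had a permutation p of 0.00409 (1e+05 resamples, genes not being independent replicates), so incomplete silencing of the X chromosome in the mutants, which was not tested, stays open.

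Fewer probe sets changed with age in mutants (667) than in wild type (7438), but without mutant replicate 1 or 2 of 17 dpp the mutant count was 6951 or 6138 (wild type then 8575 or 8339), and without wild-type replicate 1 or 3 of 14 dpp the wild-type count was 1286 or 1576 (mutants then 391 or 592). The array sets may account for many of the falls, since 73.97% of the 5750 falls in wild type were at least 0.5 times as large between the set 3 and set 1 mutant arrays of 17 dpp, as were 42.42% of the 1688 rises. Scaling stays open beside the sets, since a common median alone left 1315 falls, and 5430 of the 5750 kept their sign with the array set block. Absence of transcripts that rise in wild type was examined by the interaction, which compares genotypes within sets. With the block it was lower for 5 of 23 lists fixed in advance, the pachytene, energy, axoneme, piRNA and retrogene lists (lowest adjusted p = 0.0356 with an estimated correlation). That is the same pattern stated for lists, so it places part of the pattern in these lists and gives no cause. The age differences on set 1 correlated across probe sets at 0.0118 with the set 3 minus set 2 differences, probe sets not being independent replicates.

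Other divisions of the same arrays into groups of equal sizes bear on the counts. For the genotype difference at 14 dpp chance can be excluded, as 1 of 56 divisions, the real one, gave as many calls as 68, and the highest other gave 1. Among the 8 divisions that part all 3 same-numbered pairs, which are not shown to be true pairs, the highest other gave 0. When exchanges stayed within array sets 1 of 24 did so (128, highest other 0). At 17 dpp chance could not be excluded by this count, as 18 of 100 divisions gave 1854 or more and the highest gave 9168, which points to a structure of the samples. In 17 of those 18 the 3 set 1 arrays lay in 1 group, and among the 81 divisions that split set 1 the highest other gave 57.

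With exchanges within array sets and the set as a block, chance can be excluded at 17 dpp, as 1 of 100 divisions gave 6550 calls and the highest other gave 5331. That division exchanged mutant replicate 5 with wild-type replicate 4 and so parted set 3 by the Gapdh ratio (18.5 and 7.29), again a structure of the samples. With the Gapdh ratio as a covariate it gave 1437 calls, but the exchanges of mutant replicate 4 with wild-type replicates 2 and 3 then gave 4861 and 4715, so some structure remained. 

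Divisions that mix the array sets carry the set differences in their spread, so their counts bear less on chance than those within sets. For the interaction 2 of 100 mixed divisions gave 71 or more, the highest other giving 814 by placing the 3 set 1 arrays of 17 dpp in 1 group, a structure of the samples. With exchanges within sets and the block 2 of 100 gave 416 or more. Exchanged genotype labels also remove the genotype difference of each age, so these divisions cannot exclude chance for the interaction by itself. The other of these 2 gave 2298, and it kept the labels of 17 dpp and exchanged 6 of the 8 at 14 dpp, so that the genotype differences of both ages largely added up. Divisions that moved set 3 arrays gave at most 2. For the mean over both ages 2 of 100 mixed divisions gave 964 or more (highest other 2043, of the same kind), and within sets 1 of 100 gave 2991 (highest other 552), so chance can be excluded. For age chance can be excluded in wild type (1 of 56 divisions, 7438, highest other 6457) and in mutants (1 of 100, 667, highest other 0), but the array sets follow age, so this says nothing on them, and no divisions within sets were run for age. The division with 6457 put 3 set 3 arrays against the rest, and the blocked count was 2654.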

How the results depend on the processing

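The settings with the array sets, the Gapdh ratio or set 3 left out or rescaled were chosen after the data were seen. All other settings were fixed before. Of the values of named genes under settings other than leaving out an array, 1137 kept their direction and side of the threshold, 157 lost and 4 gained a call and 2 reversed. When single arrays were left out 1124 kept both and 172 lost the call. For the fixed lists 679 kept both, 72 lost and 52 gained a call and 2 reversed, and for the X and Y sets 70 kept both, 14 lost and 2 gained a call and 4 reversed. Low signal limits the folds. Of 49 genes lower at 14 dpp 24, and of 892 lower at 17 dpp 227, had a mutant mean below the lowest of the arrays' 40th percentiles (49.2), and 38 of the 311 higher ones had a wild-type mean below it, so folds there depend on the background, as do most of the largest differences named for age and the interaction. The 40th percentiles of the other arrays ran up to 93.4, so the folds of more genes may depend on it. Except where a construction is named, the cause was not tested.

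The array set block gave 128 calls for genotype at 14 dpp, 6550 at 17 dpp, 416 for the interaction, 2654 for age in wild type and 2991 for genotype over both ages. With quantile normalization added it gave 161, 5889, 389, 2413 and 3129, and 411 for age in mutants. With the Gapdh ratio added it gave 165, 8008, 929, 4105 and 4697, and 7985 at 17 dpp with the ratio in set 3 alone. In these 4 fits rises outnumbered falls at 17 dpp. Without the set 3 arrays the counts were 233 at 14 dpp, 481 for the interaction, 3661 for age in wild type, 2269 in mutants and 2661 over both ages. Within single sets they were 31 at 14 dpp in set 2, 990 and 4006 at 17 dpp in sets 1 and 3, and 759 and 238 for age in wild type and mutants in set 1.

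Array weights gave 5357 at 14 dpp, mostly higher (3409) where the others were mostly lower, 413 for the interaction, 17593 and 12473 for age in wild type and mutants, and 2754 over both ages. Only the arrays of the groups compared gave 177 at 14 dpp, 862 at 17 dpp and 205 for age in mutants. Adding 16 or 64 before log2 gave 177 or 280 for the interaction and 1521 or 2856 for age in mutants, quantile normalization 1316 and the stricter filter 1101 for age in mutants, and a common median 3716 and 1724 for age in wild type and mutants. Rises then outnumbered falls (2401 to 1315 and 1395 to 329), as they did in mutants with quantile normalization (792 to 524). Replicate numbers are not shown to pair at either age (correlations of −0.227 to 0.777 at 17 dpp). The replicate block gave 39 for the interaction, 1856 for age in mutants, 57 at 14 dpp and 2311 at 17 dpp. It moved the other 4 counts by less than 1.5 times. Set 3 on the common trimmed mean left all 6 counts within 1.5 times (70, 1837, 64, 6306, 486 and 975). Without probe sets that match several transcripts the genotype differences of Tesmin, Psmc3ip and Nek2 and the interaction of Gm7444 had no value. At a threshold of 0.025 the counts were 27 for the interaction and 3991 and 200 for age in wild type and mutants, which the threshold itself explains. The correlation of the genotype differences at both ages was 0.434 with the array set block, and that of the age differences 0.333 within set 1.

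Apoe reversed for age in wild type, to 0.11 with the array set block and quantile normalization and to 0.073 with the block and the Gapdh ratio. Under the same block alone the median of the Y-linked list and that of all Y-linked genes reversed to −0.81 for age in wild type, and for age in mutants all X-linked genes reversed to −0.14 and all Y-linked genes to −0.13. The Y-linked list's median for age in mutants shrank to 0.003, and it was its set test that reversed, from up to down. The median of all X-linked genes for age in mutants (0.021) is the same by fry, whose direction was the reverse of the set test's.

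Leaving out single arrays gave from 24 (wild-type replicate 2 of 14 dpp) to 78 calls for genotype at 14 dpp, from 1206 (wild-type replicate 5) to 3947 (wild-type replicate 1) at 17 dpp, from 0 (wild-type replicate 1 of 14 dpp, with 1198 at an unadjusted p under 0.05 in limma) to 133 for the interaction, from 1286 (wild-type replicate 1 of 14 dpp) to 12474 (wild-type replicate 1 of 17 dpp) for age in wild type, from 97 (mutant replicate 3 of 14 dpp) to 6951 (mutant replicate 1 of 17 dpp) for age in mutants, and from 666 to 1175 over both ages. The correlation of genotype differences ran from 0.257 to 0.409 and that of age differences from 0.666 to 0.776.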

Other observations

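The enrichment tests of gene families and of the genes near Mybl1, and the array comparisons by age, were chosen after the data were seen, whereas the test of clone names was not. The tests over genes in this section count genes as independent, so their p values do not measure the spread between arrays.

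Several families of genes with a shared symbol, some of them of motile cilia, held many falls in mutants at 17 dpp. Of 245 families of at least 8 tested genes that share the letters of their symbol, 7 held more falls than other genes by Fisher's exact test with adjustment over the families, and none held more rises (adjusted p = 1 for each). Of 22 Cfap genes, which encode cilia and flagella proteins, 16 fell (adjusted p = 2.04e-13), among them Cfap206 (−6.31) and Cfap43 (−4.23). Of 8 Dnah genes, the axonemal dynein heavy chains, 5 fell (adjusted p = 0.00197), of 106 Ccdc genes 24 (adjusted p = 8.48e-07), such as Ccdc89 (−6.36 ± 0.39) and Ccdc39 (−4.35 ± 0.45), a ruler of the axonemal repeat, and of 39 Ttc genes 11 (adjusted p = 0.00075), such as Ttc29 (−6.05). Of 19 Spata genes 7 fell (adjusted p = 0.00296), of which Spata4 had −7.11 ± 0.38 and had already fallen at 14 dpp (−4.41 ± 0.43, adjusted p = 7.82e-05). Of 10 Spag genes 5 (adjusted p = 0.00535) and of 22 Adam genes 6 fell (adjusted p = 0.0449), the latter Adam2, Adam5, Adam32, Adam3, Adam18 and Adam1b. Some of these genes belong to the fixed axoneme list. Outside that list 15 of 21 Cfap (adjusted p = 2.1e-12), 23 of 104 Ccdc (2.16e-06), 11 of 39 Ttc (0.000656) and 7 of 19 Spata genes (0.00339) fell and passed, whereas the Dnah (3 of 5, 0.0707) and Spag families (3 of 7, 0.151) did not pass. The Adam family has no member in that list and kept its 6 of 22 falls, so only the adjustment over families moved it past the threshold (0.0584). Outside all fixed lists 4 of 20 Adam genes fell (adjusted p = 0.479), while the Cfap, Ccdc, Ttc and Spata families still passed (up to 0.0171).

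The array set block left 19 Cfap, 37 Ccdc, 13 Ttc and 6 Dnah genes lower, and these 4 families passed (adjusted p from 3.2e-13 to 0.0104), whereas 7 Spata (0.082), 5 Spag (0.0734) and 6 Adam genes (0.338) did not suffice. In the same order Cfap, Ccdc, Ttc and Dnah counts were with quantile normalization 17, 28, 12 and 5, and on a common median 16, 25, 11 and 5. With the block 8 families passed, 4 of them only with it. The Cep family, of centrosomes, the Ift family, of intraflagellar transport, the Wdr family, of WD repeat proteins, and the Bbs family, of Bardet-Biedl syndrome, held 7 of 36, 4 of 14, 7 of 58 and 1 of 8 falls without the block and did not pass (adjusted p = 0.129, 0.195, 0.826 and 1), but 20, 13, 16 and 5 with it (adjusted p = 1.07e-08, 8.53e-10, 0.0207 and 0.0249).

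Genes still named after clones of adult testis cDNA libraries fell often at 17 dpp. Of 366 such genes 95 fell (26%), against 797 of 14941 others (5.33%), an odds ratio of 6.22 (Fisher's exact p = 9.28e-37), and 1 rose, against 310. At 14 dpp 9 of 366 and 40 of 14941 fell (odds ratio 9.39), and under the array set block 110 fell at 17 dpp (odds ratio 3.48). Many uncharacterised genes of this kind may thus be transcripts of meiotic cells, a hypothesis that this count alone does not settle. In whole testes a lower share of such cells cannot be told apart from less transcript within them.

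The repro9 allele could carry a linked haplotype of another strain that changes genes nearby. Among the 45 tested genes of the 100 on each side of Mybl1 in map order, 5 were called at 17 dpp (11.1%) and 0 at 14 dpp, against 7.85% of other genes at 17 dpp, a ratio of 1.42. A rate 2 times that of other genes would give 7.06, and 5 or fewer then had a binomial p of 0.27, while 5 or more at an equal rate had 0.277. The count therefore decides neither way, and a linked haplotype stays open.

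Single probe sets marked the array sets and ages irrespective of genotype. On the 3 set 1 arrays of 17 dpp 142 probe sets lay more than 1 log2 unit outside all other arrays (139 lower and 3 higher), as did 1 on the set 1 arrays of 14 dpp, 360 on set 2 and 3050 on set 3. A probe set of Nipbl ran from 7.07 to 7.29 on the former 3 arrays and from 11.05 to 13.04 elsewhere, and one of Pik3cd from 12.57 to 12.71, against 8.23 to 10.04.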
